A study of Mus musculus with 9 samples.

How the data were processed

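Poly-A or rRNA-depleted RNA of mouse aorta was measured in 9 libraries, 5 WT and 4 Apoe_KO. The labels' protocol describes removal of ribosomal RNA from total RNA before library preparation, while the labels' molecule field names polyA RNA, and the conflict was left open. Per the submitters' processing notes, the genome build was GRCm38 and limma was among the tools, with no role or version. The aligner, the counting program, the annotation and the strandedness are not given in the sources used here.

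The authors deposited 1 table of 33293 gene identifiers with a column per library, and its header gives no unit. The deposited values were taken to be FPKM from the values themselves. Each value times the gene's length over the union of its exons in GENCODE mouse release 21 was a whole number of reads at a single depth per library. Within 0.1 read, 97.6% to 97.9% of values worth up to 50 reads were whole, and 95.2% to 95.5% of all values, where chance gives 20%. The depths were 17.0 to 19.8 M reads or fragments, and the sources do not say which were counted. Of the identifiers 33240 were in that annotation and 53 were not, and 2861 were 0 in every library. Symbols, positions and overlaps came from the same annotation. No column belonged to another sample and no 2 columns were identical.

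The design allowed for counts or for normalized values, and the test for normalized values was used because of the unit. Genes with at least 1 FPKM in at least 4 libraries (13383) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options), genotype as the only term and all 9 libraries. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes of low level. Gene lists (39, of which 36 had at least 5 tested genes) were fixed before the data were examined. They covered cell types of the vessel and of neighbouring tissue, immune cells, lipid metabolism, matrix, stress responses, clock, cell cycle, sex-linked, substrain and Apoe-adjacent genes. They were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with fry. An exact permutation test of each list's mean per library, two-sided over 126 splits, was added after the data were seen. The names Ahsp and Apoc2 were not matched to a row and are not analysed here.

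The genes named were set by a rule fixed in advance. It took Apoe, then the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 FPKM and groups that did not overlap, then up to 4 called members per list by smallest p or, where none was called, the 2 of smallest p. Of the genes it chose, 6 are not reported here, though they remain in every count of genes, of comparisons and of single libraries far from their group. Genes named beyond it are said to have been chosen after their values were seen.

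The same steps were tested on simulated data for 4 Apoe_KO against 5 WT libraries. In 5 simulations, reads were drawn for the real genes (13568 to 13583 passing the filter) at the real means and depths. In each, 200 genes and a further list of 20 were changed. All genes had the same dispersion of 0.0134, and no library was made to stand apart, so the real data may do less well. Of 100 genes changed 1.5-fold, 73.4% were recovered, and of 100 changed 2-fold, 98.6%, with 0 of the wrong sign. False calls made up 7.02% of calls, above the threshold of 5%. Camera called the changed list of 20 genes in 5 of 5 simulations and 0 of 175 unchanged lists, whose genes were drawn independently.

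The alternatives planned were the replicate number as a block, leaving out each library in turn, a pseudocount of 0.1, no filter, a filter of 10 FPKM, median centring, quantile normalization, library weights, a minimum absolute log2 fold change of 1, and the estimated correlation. Leaving out WT 2 and Apoe_KO 4 together, and voom on the recovered reads, were chosen after seeing the data. The depths set what could be seen, since 1 read on a gene of 2 kb was worth 0.0253 to 0.0294 FPKM and the filter of 1 FPKM lies far above it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and draw the plots.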

Results

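RNA from whole aorta was sequenced from male mice aged 7 to 8 weeks on normal chow. There were 5 libraries from C57BL/6J mice (WT) and 4 from mice that lack Apoe (Apoe_KO), the gene of apolipoprotein E, which carries lipid in plasma lipoproteins and is bound by receptors that clear them. The values were FPKM per gene. They corresponded to whole reads at depths of 17.0 to 19.8 M reads or fragments per library, so that 1 read on a gene of 2 kb was worth 0.0253 to 0.0294 FPKM. The labels do not say whether each library came from a separate animal, and all p-values therefore measure only the spread between these samples. The question was which transcripts differ between aortas of the 2 genotypes on normal chow.

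Apoe itself (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand, GRCm38, 2138 exonic bases) was at 563 ± 54.0 FPKM in WT (SD, n = 5) and at 6.22 ± 0.401 FPKM in Apoe_KO (SD, n = 4). The knockout mean was 1.11% of the WT mean, a ratio of 90.4. Every library followed its label, with 20665 to 26292 reads in WT and 227 to 265 reads in Apoe_KO. The log2 fold change was -6.28 (SE 0.082) and the limma adjusted p was 5.63e-11. A two-sided exact permutation test over all 126 splits gave p = 0.0159, the smallest it can give. Which part of the gene the allele removes is not given in the sources used here.

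**Figure D1:**
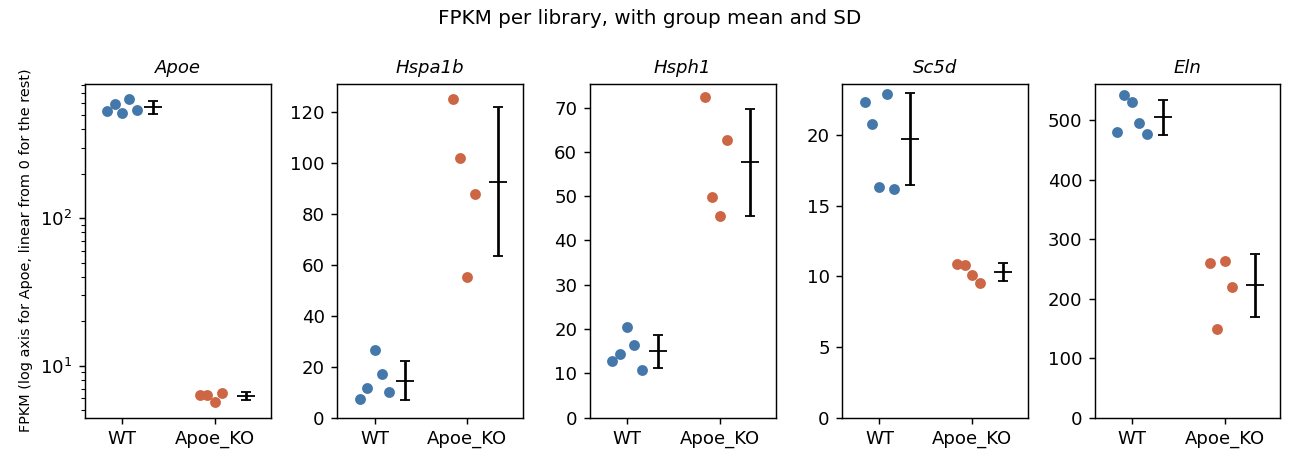
FPKM of 5 genes in each library, with WT in blue and Apoe_KO in orange, and the group mean with its SD as a black bar; the axis is logarithmic for Apoe and linear from 0 for the other genes. The WT and Apoe_KO libraries did not overlap for any of these genes, and Apoe had a mean of 563 FPKM in WT against 6.22 in Apoe_KO.

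Of 13383 tested genes, 459 were called higher and 524 lower in Apoe_KO (limma, FDR 0.05). The strongest increases included heat-inducible chaperones: Hspa1b rose from 14.5 ± 7.55 to 92.4 ± 29.2 FPKM (log2 fold change 2.66, SE 0.35), Hspb1 from 96.4 ± 18.0 to 457 ± 112 FPKM (2.22, SE 0.17), and Hsph1 from 14.9 ± 3.69 to 57.6 ± 12.2 FPKM (1.88, SE 0.19), with SDs over 5 WT and 4 Apoe_KO libraries. Hspa1a had a log2 fold change of 2.19, but it is nearly identical to Hspa1b and reads could have been split between them. Errfi1, a feedback inhibitor of the EGF receptor, rose by 1.88 on the log2 scale, the metallothionein gene Mt2 by 1.83, the palmitoyltransferase gene Zdhhc23 by 1.72 and the nuclear receptor gene Nr4a3 by 1.71. The list was completed by Gm45104, a gene on chromosome 7 that rose from 0.042 to 2.32 FPKM, and by Snora41 with a log2 fold change of 1.66, a short small nucleolar RNA whose value is uncertain. Mt2 and Hspa1a overlap antisense genes, and the strandedness of the counting is not stated. Mt2 was no longer called without WT 2 and Apoe_KO 4 (adjusted p = 0.0694).

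After Apoe, the largest decreases were of Apoc1, an apolipoprotein gene beside Apoe, which fell from 57.8 ± 11.6 to 7.39 ± 2.94 FPKM (log2 fold change -2.84, SE 0.21), and of Cyp2f2, a cytochrome P450 gene also on chromosome 7, which fell from 16.9 ± 4.0 to 3.14 ± 1.23 FPKM (-2.13, SE 0.23). Lep, which encodes the adipocyte hormone leptin, had a log2 fold change of -1.74, the apelin receptor gene Aplnr -1.51, and Rrad, a small GTPase gene, -1.29. Eln, the gene of elastin, fell from 505 ± 29.8 to 223 ± 53.3 FPKM (-1.21, SE 0.16). The amino acid transporter gene Slc1a5, on chromosome 7, fell by 1.18 on the log2 scale. The unnamed gene Gm20369 was at -1.32 and Mir6392, a microRNA gene too short for a firm value, at -1.97, and both lie within the bounds of Pnpla3, itself called lower. Cyp2f2, Rrad and Eln overlap antisense genes and are uncertain to that extent. Lep lost its call without WT 1, WT 2, WT 4 or Apoe_KO 3 (adjusted p = 0.0563, 0.0592, 0.0698 and 0.0912), and Mir6392 without WT 1, WT 4, Apoe_KO 1, Apoe_KO 3 or Apoe_KO 4 (0.0547, 0.0631, 0.0517, 0.0769 and 0.0599).

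**Figure D2:**
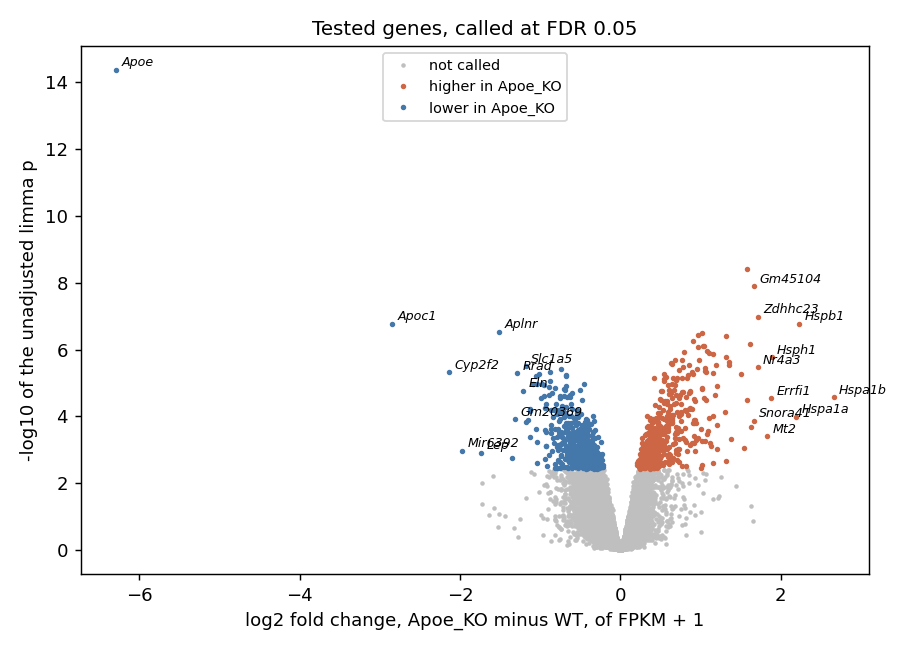
Each point is 1 of 13383 tested genes, with the log2 fold change (Apoe_KO minus WT, of FPKM + 1) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Orange points are the 459 genes called higher, blue points the 524 called lower, and the labels mark Apoe and the named genes of largest change.

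The called genes were mostly modest changes, with a median absolute log2 fold change of 0.49, and 54 of those higher and 23 of those lower reached an absolute value of 1. In 916 of the 983 called genes the libraries of the groups did not overlap, whereas over all tested genes 12.4% were so separated and chance gives 1.59%. The balance of higher and lower calls depended on scaling. The genes called again with median centring (720) or quantile normalization (637) all kept their direction. The deposited FPKM gave 46.7% of calls as higher, whereas median centring called 630 higher and 269 lower (70.1% higher) and quantile normalization 485 higher and 240 lower (66.9% higher). Single libraries also moved the counts by over 1.5 times. Without Apoe_KO 3 they were 208 higher and 174 lower, without WT 4 260 and 226, and without Apoe_KO 1 287 and 337, while the number lower was 290 without WT 1, 283 without WT 2, 320 without WT 5 and 331 without Apoe_KO 4.

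Among the libraries, WT 2 and Apoe_KO 4 stood apart through lymphocyte transcripts. Their B and plasma cell list means were 3.72 and 3.10 above the WT mean on the log2 scale, and their T and NK cell means were 1.73 and 1.59 above it. They lay at the far end of the first principal component (30.5% of the variance), and the second (27.3%) separated the genotypes. Spearman's rho between libraries, across genes, ran from 0.908 to 0.982. With both of these libraries left out, 206 genes were called higher and 170 lower, and 339 of these 376 were also called with all libraries.

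Of 36 gene lists fixed before the data were examined and large enough to test, 14 were called by limma's camera with a preset correlation of 0.01, 8 as higher and 6 as lower, and 0 with an estimated correlation (lowest adjusted p = 0.177). The fry test called 5 lists for a joint direction: heat shock, the unfolded protein response, sterol synthesis, fatty acid synthesis and the genes beside Apoe. In those 5 lists the mean of each Apoe_KO library lay beyond every WT library (two-sided exact permutation p = 0.0159, the smallest possible, and 0.114 after adjustment). The number of lists that camera called was no larger than other groupings gave: 68 of 100 splits of the same libraries called at least 14.

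Genes of the heat shock response, chaperones that refold damaged proteins, rose together. Of 12 tested members 10 were higher and 0 lower, and 12 were higher when adjusted over the list alone. Their median log2 fold change was 0.93 (camera adjusted p = 7.09e-18; adjusted p = 0.177 with an estimated correlation). Besides the genes above, Hspa8 rose from 251 ± 26.5 to 530 ± 54.7 FPKM and Hsp90aa1 from 115 ± 13.5 to 235 ± 42.4 FPKM (SD, 5 WT and 4 Apoe_KO libraries). Hspa8 shares its transcript with small nucleolar RNA genes. In the unfolded protein response of the endoplasmic reticulum, 7 of 19 members were higher and 0 lower, and 9 were higher and 1 lower when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 5.40e-08; adjusted p = 0.317 with an estimated correlation). The chaperone gene Hspa5 rose from 103 ± 7.50 to 154 ± 20.05 FPKM and Herpud1, of endoplasmic reticulum protein degradation, from 44.2 ± 2.42 to 69.3 ± 4.29 FPKM. Dnajb9 and Manf had log2 fold changes of 0.40 and 0.38, and Manf overlaps Rbm15b. Immediate early genes, which respond to stimuli within minutes, were, like the heat shock genes, fixed in advance as a list of sample quality. They had 3 of 20 members higher (Nr4a3, Maff at 1.51 and Ier3 at 0.87) and 0 lower, or 3 higher and 1 lower when adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.00130; adjusted p = 0.75 with an estimated correlation), but no Apoe_KO library mean lay above every WT library, and without WT 1 the median was 0.017 (adjusted p = 0.0482) and without Apoe_KO 4 0.13. The oxidative stress list was not called (adjusted p = 0.0527), but was called higher without WT 1 (0.0460), WT 3 (0.0461), WT 4 (0.0286), Apoe_KO 1 (0.0266) or Apoe_KO 3 (0.0297), with the replicate block (0.0246) and with no filter (0.0298). It had 2 of 18 members higher by either adjustment, adjusted over the list alone or over all genes. These were Nox4, an NADPH oxidase gene, at 0.52 and Sod3, the extracellular superoxide dismutase gene, at 0.31.

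Genes of the sterol synthesis list fell. Of 23 tested members 12 were lower and 0 higher, and 21 were lower when adjusted over the list alone, with a median log2 fold change of -0.60 (camera adjusted p = 3.04e-11; adjusted p = 0.543 with an estimated correlation). Idi1, which makes the isoprenoid precursor of sterols, fell from 8.41 ± 1.69 to 3.36 ± 0.428 FPKM and Sc5d from 19.7 ± 3.26 to 10.3 ± 0.629 FPKM (SD, 5 WT and 4 Apoe_KO libraries). Acat2, for cytosolic acetoacetyl-CoA thiolase, had a log2 fold change of -0.69. In fatty acid synthesis 4 of 14 members were lower and 0 higher, and 7 were lower when adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.000112; adjusted p = 0.75 with an estimated correlation). Thrsp fell from 311 ± 72.2 to 178 ± 26.7 FPKM, and Fads1, Pnpla3 and Acss2 had log2 fold changes of -0.45, -1.36 and -0.92. White adipocyte markers were lower beside them, in 3 of 14 members and 0 higher, or 7 lower when adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.000737; adjusted p = 0.75 with an estimated correlation). They were Lep, Agpat2 at -1.05 and Plin1, of the lipid droplet coat, at -0.56. Idi1, Agpat2 and Acss2 overlap antisense genes and Pnpla3 a gene on its own strand. With the adipocyte mean as a covariate the sterol median was -0.56, but the median SE of its genes grew from 0.13 to 0.19 and 0 of them were called. The fatty acid synthesis calls also went from 4 to 0 with that covariate (median -0.41, camera adjusted p = 0.0385, median SE from 0.19 to 0.30) and to 0 without WT 2 and Apoe_KO 4 (median -0.46), where 6 sterol genes were called. Liver X receptor targets and cholesterol efflux genes as a list were not called (median -0.080, adjusted p = 0.972), although 2 of 16 members were lower, or 3 when adjusted over the list alone. These were Srebf1, a regulator of lipid synthesis, at -0.60 and the desaturase gene Scd2 at -0.78.

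Lipid uptake and foam cell genes were not called (median -0.14, adjusted p = 0.754). One of the 14 members was higher, Scarb2 at 0.41, and another lower, the fatty acid binding protein gene Fabp5, which went from 23.8 ± 4.04 to 12.2 ± 0.991 FPKM, and the counts were the same when adjusted over the list alone. Fatty acid oxidation was not called (adjusted p = 0.716), with 1 of 18 members higher and 0 lower by either adjustment, and its median of -0.068 and mean of -0.012 differed in sign from its test. No member passed in oxidative phosphorylation (27 tested, median -0.083), the mitochondrially encoded genes (13, median -0.11) or brown adipocyte genes (14, median -0.16), by either adjustment, and the adjusted p were 0.796, 0.972 and 0.972. The members of smallest p were Atp5o at -0.22 and Ndufb3 at -0.16, mt-Nd3 at -0.24 and mt-Co2 at -0.19, and Acot11 at -0.52 and Slc27a2 at 0.42. Oxidative phosphorylation was called lower without Apoe_KO 2 (median -0.21, adjusted p = 0.000111), as were the mitochondrially encoded genes (median -0.25, adjusted p = 0.0332), and oxidative phosphorylation also with quantile normalization (adjusted p = 0.0294). Apoe_KO 2 and WT 3 had the highest mitochondrially encoded means, 0.47 and 0.36, and shares of FPKM from mitochondrial genes, 28.7% and 28.2%.

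Among genes of the vessel wall, smooth muscle contractile markers had 3 of 20 members higher and 0 lower, and 7 higher when adjusted over the list alone, with a median log2 fold change of 0.17 (camera adjusted p = 2.86e-05; adjusted p = 0.75 with an estimated correlation). Des, the desmin gene, rose from 23.8 ± 1.93 to 31.6 ± 3.33 FPKM, and the integrin gene Itga8 and the actin-binding gene Synpo2 had log2 fold changes of 0.48 and 0.44. Without Apoe_KO 1 the median of this list was 0.10. Elastic fibre and collagen genes moved both ways, with 3 higher and 4 lower of 27, or 3 and 6 when adjusted over the list alone, and the list was not called (median -0.15, adjusted p = 0.972). The lower members included Eln, the microfibril gene Mfap2 at -0.64 and Sparc, a collagen-binding matrix protein gene, which fell from 1257 ± 87.6 to 871 ± 123 FPKM, whereas the proteoglycan gene Vcan was higher at 0.37. Of the matrix proteases and inhibitors 5 of 17 were higher and 2 lower, or 6 and 2 when adjusted over the list alone, with a median of 0.039 (camera adjusted p = 0.0148; adjusted p = 0.75 with an estimated correlation). Those higher included Adamts1 at 0.92, a protease gene, Plat at 0.42, which encodes the tissue plasminogen activator, and Timp3 at 0.36, a metalloprotease inhibitor gene. That list was not called without WT 2 (adjusted p = 0.0536) or Apoe_KO 3 (0.0788) or with quantile normalization (0.154), and its median, near 0, was 0.12 without Apoe_KO 1. Of 11 chondrogenic and osteogenic genes 2 were higher, Spp1 at 1.01, the osteopontin gene, and Mgp at 0.47, an inhibitor of calcification, and 1 more was lower when adjusted over the list alone. The list was not called (adjusted p = 0.227). Fibroblast markers had 0 of 15 called by either adjustment (median 0.049, adjusted p = 0.392), with Pi16 at 0.34 and Dpep1 at 0.36. Antisense genes overlap Des, Itga8, Timp3, Eln and Pi16, and Gm42793 overlaps Spp1.

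**Figure D3:**
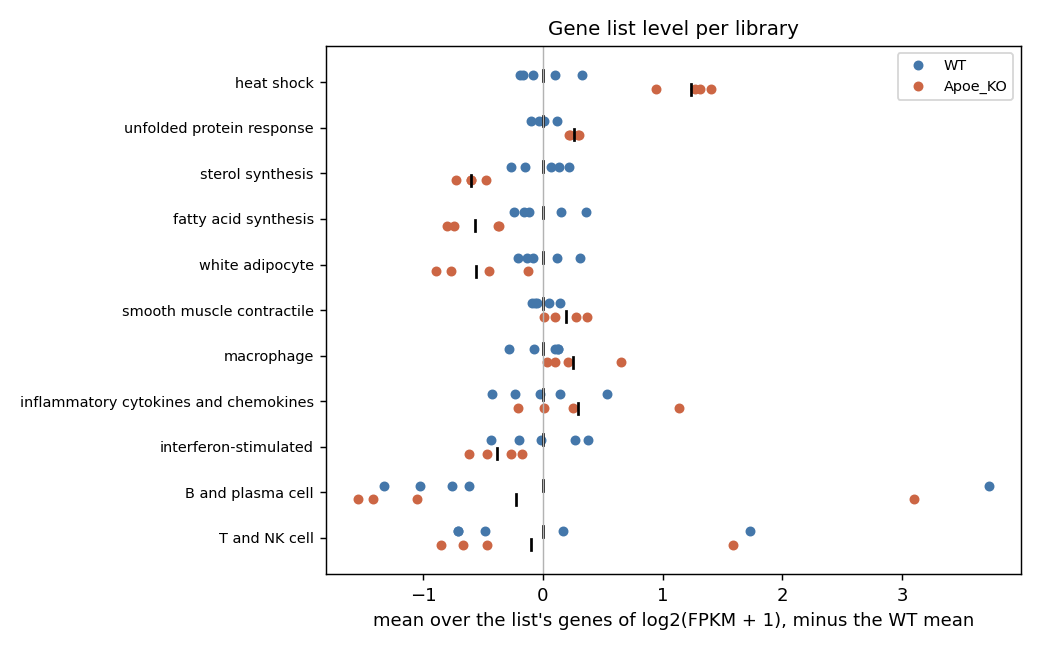
Each point is 1 library, WT in blue and Apoe_KO in orange, at its mean of log2(FPKM + 1) over a gene list minus the WT mean, with the group mean as a black bar. The heat shock means of Apoe_KO lie from 0.94 to 1.40, above every WT library, and WT 2 and Apoe_KO 4 lie at 3.72 and 3.10 for B and plasma cells.

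Immune markers must be read with the lymphocyte signal of WT 2 and Apoe_KO 4. Of 22 macrophage markers 3 were higher and 0 lower, and 5 were higher and 1 lower when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 4.34e-05; adjusted p = 0.75 with an estimated correlation). They were Lyve1 at 0.81, a marker of resident vessel-associated macrophages and lymphatic endothelium, Cd14 at 1.2 and the Fc receptor gene Fcgr3 at 0.62. The Apoe_KO 4 library had the highest macrophage mean, 0.66, against -0.28 to 0.13 in WT, and the exact permutation p of the list mean was 0.175. Without Apoe_KO 4 the macrophage median was 0.075 (adjusted p = 0.00688), and without WT 3 it was 0.13. Inflammatory cytokines and chemokines had 2 of 12 members higher by either adjustment, Nfkbia, an NF-kappaB inhibitor gene that NF-kappaB induces, which rose from 41.4 ± 5.46 to 96.3 ± 15.6 FPKM, and the chemokine gene Ccl9 at 1.02, with a median of 0.27 (camera adjusted p = 0.00575; adjusted p = 0.75 with an estimated correlation). Apoe_KO 4 had the highest mean here too, 1.14, and without it the median was 0.037 and the list was not called (adjusted p = 0.0762). Nor was it called with library weights (0.0580) or without WT 2 and Apoe_KO 4 together (0.0583). Only 12 of its 20 genes were tested, and Il6, Il1a, Il1b, Tnf, Ccl3, Ccl4, Cxcl2 and Nlrp3 did not pass the filter. Il6, chosen after its values were seen, was at 0.320 ± 0.301 FPKM in WT and 3.40 ± 3.32 in Apoe_KO (SD). It was at 0.042 FPKM in Apoe_KO 1. The means of Tnf, Ccl3 and Ccl4 were lower in Apoe_KO, and those of the other untested members higher. Interferon-stimulated genes had 1 of 19 members lower and 0 higher, or 3 lower when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.0129; adjusted p = 0.847 with an estimated correlation). Without Apoe_KO 1 this list was not called (adjusted p = 0.144), and without WT 1 its median was -0.27.

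No member of the lymphocyte, granulocyte, antigen presentation or endothelial activation lists passed, by either adjustment, and none of these lists was called. T and NK cell genes had a median of 0.092 and a mean of -0.099 (7 tested, adjusted p = 0.972), with Nkg7 at -0.65 and Gzma at -0.27. B and plasma cell genes had a median of -0.30 and a mean of -0.23 whereas their test pointed up (7 tested, adjusted p = 0.972), with Ighm at -0.34 and Jchain at -0.30. Neutrophil and mast cell genes had a median of 0.027 and a mean of -0.060 (7 tested, adjusted p = 0.825), with S100a9 at -0.69 and Mcpt4 at 0.18. Antigen presentation genes had a median of -0.11 (14 tested, adjusted p = 0.972) and were called lower without Apoe_KO 4 (median -0.37, adjusted p = 0.0209) or without WT 2 and Apoe_KO 4 together (0.0430). Tap2 was at -0.23 and Psmb9, which overlaps Tap1, at -0.47. Endothelial activation and leukocyte adhesion genes had a median of -0.0010 and a mean of 0.064 (13 tested, adjusted p = 0.972), with F11r at -0.35 and Ackr1 at -0.36. Endothelial markers were lower in 1 of 17, or 3 when adjusted over the list alone, namely Kdr, the gene of a VEGF receptor, at -0.58. The list was not called (median -0.19, adjusted p = 0.121), but was without WT 1 (-0.30, adjusted p = 0.00409) or Apoe_KO 4 (-0.34, adjusted p = 0.0132), with no filter (0.0374), the filter of 10 FPKM (0.0321), quantile normalization (0.0103) or library weights (0.0207), or without WT 2 and Apoe_KO 4 together (0.0115). Without Apoe_KO 1 its median was -0.12 (adjusted p = 0.579), and with median centring also -0.12. Cytosolic ribosomal protein genes had 0 of 28 members called by either adjustment and a median of 0.13 (camera adjusted p = 0.000645; adjusted p = 0.852 with an estimated correlation), with Rpl4 at 0.24. WT 2 and Apoe_KO 4 had the highest means of that list in their groups, 0.26 and 0.55, and without Apoe_KO 4 (adjusted p = 0.279) or with quantile normalization (0.0872) it was not called.

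Markers of tissues around the vessel varied between libraries. Schwann and nerve genes had 2 of 15 members lower and 0 higher, or 7 lower when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.00584; adjusted p = 0.75 with an estimated correlation). The lower members included the sodium channel gene Scn7a at -0.44, and without Apoe_KO 4 the list was not called (adjusted p = 0.0748). Erythroid genes had 0 of 7 members called by either adjustment and a median of -1.25 (camera adjusted p = 0.0463; adjusted p = 0.75 with an estimated correlation), with Bpgm at -0.50 and the globin gene Hbb-bt at -1.73. The erythroid call was lost without WT 1 (adjusted p = 0.0994), WT 3 (0.105), WT 5 (0.0938), Apoe_KO 1 (0.204) or Apoe_KO 2 (0.108), with the replicate block (0.0955), with a pseudocount of 0.1 (0.0528) and with library weights (0.07997). Skeletal muscle genes had a median of -0.25 and a mean of -0.23 although their test pointed up (6 tested, adjusted p = 0.972), with Acta1 at -0.74 and Mybpc2 at 0.16. Cardiac muscle genes had a median of -0.47 (8 tested, adjusted p = 0.972), with Actc1 at -0.61 and Sln at -0.59. Neither muscle list had a called member by either adjustment. Of the liver and pancreas list 1 gene was tested, Alb at -0.99, and it was not called. Without WT 3 Alb was at -0.50. Of 4 tested Y-linked genes 0 were called, with Ddx3y at 0.23 and Kdm5d at -0.23, and Xist was at 0.0253 ± 0.0123 FPKM in WT and 0.0245 ± 0.0129 FPKM in Apoe_KO (SD, 5 and 4 libraries). Cell cycle genes had a median of -0.053 and a mean of -0.066 although their test pointed up (7 tested, 0 called by either adjustment, adjusted p = 0.972), with E2f1 at -0.11 and Mcm2 at -0.17. The genes known to differ between C57BL/6 substrains had a median of 0.055 and a mean of -0.010 (5 tested, 0 called by either adjustment, adjusted p = 0.972), with Ide and Gtf2h2 both at -0.12. Nnt, Entpd4, Fgfbp3 and Mid1 of that list did not pass the filter and were not tested. Nnt, chosen after its values were seen, was at 0.0756 ± 0.0187 FPKM in WT and 0.0531 ± 0.0233 FPKM in Apoe_KO (SD).

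Clock genes changed in both directions. Of 15 tested 5 were higher and 3 lower, or 6 and 3 when adjusted over the list alone, and the list as a whole was not called (median 0.072, adjusted p = 0.146). The repressor gene Cry1 rose from 3.64 ± 0.590 to 6.22 ± 0.574 FPKM and Nfil3 from 4.25 ± 0.890 to 10.9 ± 3.93 FPKM, while Dbp fell from 45.1 ± 3.18 to 27.6 ± 4.66 FPKM and Nr1d1 from 67.6 ± 7.77 to 38.4 ± 9.06 FPKM (SD, 5 WT and 4 Apoe_KO libraries). Dbp and Nr1d1 overlap the antisense genes Sphk2 and Thra.

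Of 28 tested genes beside Apoe on chromosome 7, 5 were lower and 0 higher, or 5 lower and 1 higher when adjusted over the list alone. Camera did not call the list (median -0.11, adjusted p = 0.1), fry did (adjusted p = 0.00656), and camera called it without WT 1 (adjusted p = 0.0454) or Apoe_KO 2 (0.0461), with no filter (0.0298) and with the filter of 10 FPKM (0.00415), while without Apoe_KO 3 the median was -0.071. Besides Apoc1, the members of smallest p were Klc3 at -0.60, Bcam at -0.47 and Ercc2 at -0.49, of which Klc3 and Ercc2 overlap each other on opposite strands. Calls were more frequent over a wider part of the chromosome. From 1 to 10 Mb of Apoe 26 of 161 tested genes were called (16.1%), against 884 of 12346 on the other chromosomes (7.16%; Fisher's exact test, two-sided, p = 0.000101). From 10 to 20 Mb the count was 14 of 139 (Fisher's exact test, p = 0.185).

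**Figure D4:**
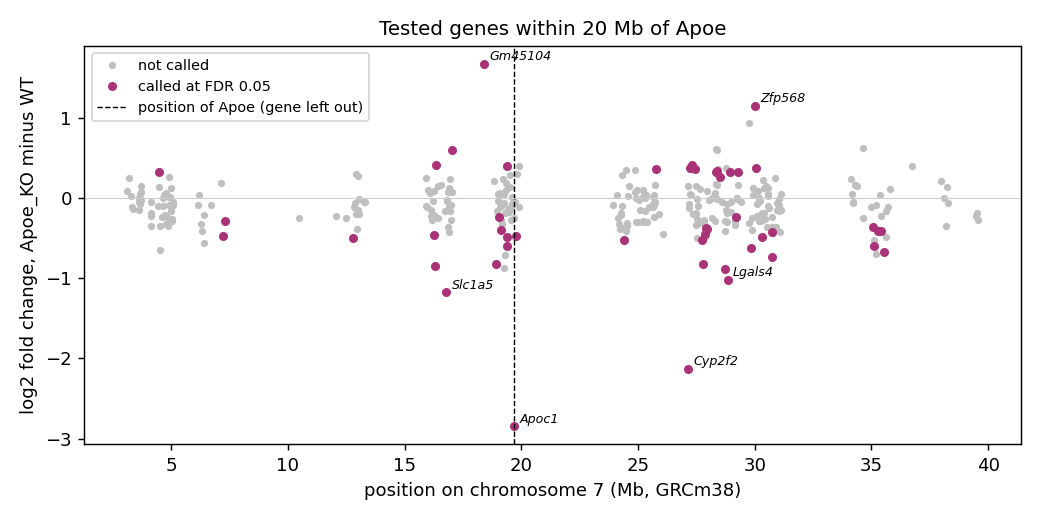
Log2 fold change (Apoe_KO minus WT) of each tested gene within 20 Mb of Apoe against its position on chromosome 7 (Mb, GRCm38), with called genes in purple, other tested genes in grey and Apoe itself left out at the dashed line. Within 10 Mb 21 of the 34 called genes were lower and 13 higher.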

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

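The tests of the chromosome 7 pattern, of the libraries rich in B-cell transcripts, of the clock arms without single genes and of other splits of the libraries were chosen only after the results they bear on had been seen.

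Single libraries lay far from the rest of their group in 24 of 288 group tests over 144 results, where chance gives about 14.4. Values are log2(FPKM + 1) for genes and differences from the WT mean for lists. WT 2 was high for Nkg7 (2.65), Ighm (7.98), Jchain (6.36), Mcm2 (2.21), Rpl4 (8.47), the B and plasma cell list (3.72), the cell cycle list (0.76) and the ribosomal protein list (0.26), and low for Nr1d1 (5.78). Apoe_KO 4 was high for Gm20369 (0.44, against 0 in the other Apoe_KO libraries), F11r (4.42), Rpl4 (8.83), the T and NK cell list (1.59), the B and plasma cell list (3.10) and the cell cycle list (0.53). Other single libraries were Apoe_KO 1, low for Srebf1 (4.29), Apoe_KO 3, high for the fibroblast list (0.23), WT 1, high for Hsp90aa1 (7.13) and low for the endothelial activation list (-0.37), and WT 5, high for the elastic fibre list (0.14). WT 3 was low for Mfap2 (3.29) and high for the mitochondrially encoded list (0.36) and for the share of FPKM from mitochondrial genes (28.2%).

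The genes called within 10 Mb of Apoe were more frequent than elsewhere. Their excess was not limited to the neighbours of the gene, since the share called from 1 to 10 Mb was 2.26 times that of other chromosomes. If poorer mapping of reads that carry another strain's variants caused all these calls, nearly all would be lower. Within 10 Mb 61.8% were (95% exact Clopper-Pearson interval 43.6% to 77.8%), and from 1 to 10 Mb 53.8% (33.4% to 73.4%). This argues against poorer mapping as the cause of all calls from 1 to 10 Mb. It cannot decide for single genes there, since calls on other chromosomes also went both ways (423 higher, 461 lower). Within 1 Mb 87.5% were lower (47.3% to 99.7%), as were 11 of 14 from 10 to 20 Mb and 9 of 10 from 20 to 40 Mb. Poorer mapping therefore stays open at those distances too. A segment of another strain that came along with the knockout allele is a candidate explanation, since as few as 0.888% of 338 windows of the same width on other chromosomes, which overlap each other, reached the share around Apoe. The strain of the allele was not tested, and genes that such a segment could change cannot be credited to the loss of Apoe.

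The mean of the heat shock list was higher in all 4 Apoe_KO libraries than in any WT library. The libraries rich in B-cell transcripts are not the cause, since 98.5% of the list's median was kept without WT 2 and Apoe_KO 4, with 9 of its genes called against 10. Glucocorticoid exposure that differed between the groups remains open. A list of 17 inducible genes, added after the data were seen, had a median log2 fold change of 0.48 (camera p = 1.98e-11, 0.0217 with an estimated correlation). Of these 8 were called higher and 0 lower, 1 of them, Hif3a, near Apoe. Some of the 17, Per1 among them, were also members of the lists fixed in advance, so the list was not wholly new. A different time of dissection cannot be told apart from genotype here: the clock output arm minus Clock and Cry1, the 2 tested genes set against it, differed by -0.49 between the groups (two-sided exact permutation p = 0.0159, the smallest possible with 5 WT and 4 Apoe_KO libraries), and by -0.40 to -0.78 without any one gene but Cry1, but Cry1 is a repressor that was counted with the positive arm, and without it the difference was -0.21 (p = 0.143). The labels give no times of collection, so an effect of genotype stays open beside both, as untested. The heat shock list was fixed in advance as a list of sample quality, as were the immediate early, mitochondrially encoded and ribosomal protein lists. Camera with the preset correlation also called immediate early (adjusted p = 0.00130) and ribosomal protein genes (0.000645) higher, but not the mitochondrially encoded genes (0.972). With the estimated correlation it called none of them. Whether quality or handling that differed between the groups caused the heat shock change was not tested.

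The mean of the sterol synthesis list was lower in all 4 Apoe_KO libraries than in any WT library. With the white adipocyte mean as a covariate 93.0% of the list's median was kept, from -0.60 (quartiles -0.74 to -0.44) to -0.56 (-0.85 to -0.48). This argues only against differences that follow that mean as the whole cause. It cannot decide on fewer adipocytes, for which the mean is only a stand-in. The mean itself also differed between the groups, with 3 of the 4 Apoe_KO libraries below every WT library. The adipocyte median moved from -0.47 to 0.023, but this is no check of the correction, since the covariate was the mean of that same list. Camera called the adipocyte list with the covariate too (adjusted p = 0.0471), but at that median of 0.023 (quartiles -0.13 to 0.28). The call therefore does not show that its genes stayed lower. The calls of single sterol genes went from 12 to 0, with a median SE of 0.19 against 0.13 before, and whether the larger SE alone ended them was not tested. Median centring kept 88.7% of the sterol median. It shifts all genes of a library by the same constant, and the median log2 fold change over all tested genes was only -0.069. It therefore argues only against a constant scaling factor as the whole cause and says nothing of scaling that depends on level. Leaving out WT 2 and Apoe_KO 4 kept 83.8%, which argues against those libraries as the whole cause, although without them 6 genes of the list were called against 12. An effect of the genotype on sterol synthesis is therefore a hypothesis that these tests leave standing, beside fewer adipocytes. Glucocorticoid exposure and time of day were not tested for this list.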

How the results depend on the processing

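The alternatives without WT 2 and Apoe_KO 4 together and with voom on recovered reads, and the tests of other splits, were chosen after the data were seen. Apoe kept its direction and call under all alternatives. Among 100 splits of the libraries, the real one included, 1 called as many genes higher (459, highest other 1) and 1 as many lower (524, highest other 1). The real grouping thus stood out for both counts. The other splits mix the genotypes, which adds spread within their groups and lowers their counts, so this does not exclude chance. For gene lists called with the preset correlation the real grouping did not stand out, since 68 of 100 splits reached 14 (highest other 22), and the estimated correlation called 0. Depth and the filter of 1 FPKM limit what is said of genes of low level.

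Genes called higher and lower, with cause not tested unless given, were 247 and 198 with no filter (30432 genes tested), 54 and 23 with a minimum absolute log2 fold change of 1 (fewer by construction), 702 and 1055 with library weights, and 206 and 170 without WT 2 and Apoe_KO 4 (fewer libraries). The number lower was 220 with the filter of 10 FPKM (4707 genes tested), 269 with median centring and 240 with quantile normalization. With voom 465 and 559 were called, and 923 of these were called in the main test. Leaving out each library gave 208 to 572 higher, 174 to 666 lower, 13 to 16 lists and log2 fold changes of the Apoe level from -6.31 to -6.23.

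With the replicate block (WT 1 to 4 paired with Apoe_KO 1 to 4) 120 genes were called higher and 61 lower, 175 of them also without the block, and 14 lists. The labels do not say whether the shared numbers pair the libraries. The deviations of same-numbered libraries correlated, across genes, at 0.26, -0.27, -0.13 and -0.22. None of WT 1 to 4 correlated best with the Apoe_KO library of its own number. These correlations showed no sign of pairing but cannot decide it.

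Of 1848 comparisons of 105 other named genes, 1611 kept direction and call, 217 lost the call, 11 gained it and 9 reversed, in 5 genes. Of 672 comparisons of 36 lists, 532 were the same, 32 lost the call, 23 gained it and 85 reversed, in 17 lists. A list's direction is that of its camera test, whose value is given here as the median log2 fold change, so the sign printed can stay while the test turns. By the sign of the median instead, 49 of 636 comparisons turned, against 85 by the test. In 0 of the 85 was the list called under either setting, and 1 median that turned was of a called list (ribosomal protein, -0.0027 without Apoe_KO 4). The cause was not tested for any reversal. Values below are medians for lists and log2 fold changes for genes.

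With quantile normalization those that reversed were E2f1 0.0097, T and NK cell 0.20, B and plasma cell -0.21, fibroblast 0.0045, skeletal muscle -0.13, endothelial activation 0.098 and fatty acid oxidation -0.087. With the replicate block those that reversed were T and NK cell -0.13, B and plasma cell -0.59, brown adipocyte -0.16, skeletal muscle -0.44, elastic fibre -0.11 and cell cycle -0.12. With median centring those that reversed were T and NK cell 0.16, B and plasma cell -0.23, skeletal muscle -0.18, endothelial activation 0.067 and cell cycle 0.015. With library weights those that reversed were T and NK cell 0.10, neutrophil and mast cell -0.056, endothelial activation -0.040, fatty acid oxidation -0.17 and elastic fibre -0.091. Without WT 2 and Apoe_KO 4 those that reversed were B and plasma cell -0.43, neutrophil and mast cell -0.11, brown adipocyte -0.041, skeletal muscle -0.41, cardiac muscle -0.38, endothelial activation -0.080, oxidative phosphorylation -0.064, elastic fibre -0.12, cell cycle -0.092 and mitochondrial -0.12. With no filter those that reversed were skeletal muscle -0.28 and endothelial activation 0.0098. With the filter of 10 FPKM those that reversed were endothelial activation -0.25, fatty acid oxidation -0.079 and circadian clock -0.11. With a pseudocount of 0.1 those that reversed were LXR target -0.083 and mitochondrial -0.11. Leaving out each library in turn gave ranges of Ighm -1.25 to 0.30, Jchain -1.12 to 0.72, Mcpt4 -0.0075 to 0.29, Mcm2 -0.35 to 0.039, T and NK cell -0.57 to 0.43. Further ranges were B and plasma cell -1.31 to 0.64, neutrophil and mast cell -0.13 to 0.14, fibroblast -0.044 to 0.094, brown adipocyte -0.40 to 0.0075, skeletal muscle -0.44 to 0.017, cardiac muscle -0.87 to -0.061, endothelial activation -0.16 to 0.19. The last ones were antigen presentation -0.37 to 0.048, LXR target -0.17 to -0.019, fatty acid oxidation -0.23 to 0.013, oxidative phosphorylation -0.21 to -0.010, elastic fibre -0.19 to -0.069, cell cycle -0.26 to 0.14, mitochondrial -0.25 to 0.0097, C57BL/6 substrain -0.071 to 0.12. Without a reversal, single libraries moved by over 1.5 times the lists of lipid uptake (-0.19 to -0.083), chondrogenic (0.071 to 0.22), oxidative stress (0.0083 to 0.081), circadian clock (0.036 to 0.11), endothelial (-0.34 to -0.12) and genes beside Apoe (-0.16 to -0.071), none of them called by camera with all libraries. The same held for genes not called with all libraries: Acta1 -1.07 to -0.26, Actc1 -1.005 to -0.13, Alb -1.22 to -0.50, Atp5o -0.36 to -0.15, E2f1 -0.17 to -0.045, Gtf2h2 -0.19 to -0.070, Gzma -0.57 to -0.13, Ide -0.14 to -0.074, Mybpc2 0.085 to 0.31, Ndufb3 -0.26 to -0.099, Nkg7 -0.93 to -0.34, Psmb9 -0.75 to -0.31, Rpl4 0.12 to 0.30, S100a9 -1.09 to -0.39, Slc27a2 0.24 to 0.57, Sln -1.11 to -0.34, mt-Co2 -0.37 to -0.054 and mt-Nd3 -0.39 to -0.15.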

Other observations

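Of the glucocorticoid-inducible list, added after the data were seen, 8 genes were called higher in Apoe_KO (limma, FDR 0.05). They are named here after their values were seen, and Per1 was also in the clock list. Mertk, a receptor gene for the clearance of dying cells, rose from 17.0 ± 1.67 to 32.9 ± 4.54 FPKM, Fam107a from 13.8 ± 4.27 to 29.1 ± 5.45 FPKM, Klf9 from 70.4 ± 5.33 to 109 ± 9.97 FPKM and Sgk1 from 27.9 ± 5.55 to 44.2 ± 7.23 FPKM (SD, 5 WT and 4 Apoe_KO libraries). Hif3a, Per1, Tsc22d3 and Sesn1 had log2 fold changes of 0.60, 0.48, 0.41 and 0.39.

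On chromosome 7, and named after their values were seen, Zfp568 (29983955 to 30028282, GRCm38), 10.3 Mb from Apoe, was higher, at 4.88 ± 0.560 FPKM in WT and 12.2 ± 2.01 in Apoe_KO, and Lgals4 (28833854 to 28841708), 9.14 Mb from it, was lower, at 4.55 ± 0.503 and 1.76 ± 0.430 FPKM (SD, 5 WT and 4 Apoe_KO libraries). Sae1 (16320234 to 16387806) was at 19.7 ± 0.481 and 26.6 ± 0.587 FPKM.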
